A study of Mus musculus with 6 samples.

How the data were processed

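Messenger RNA was measured in 6 libraries of sorted Tregs by bulk RNA sequencing. Per the labels' protocols, 500 to 1000 cells per library were lysed, cDNA was made with a SMART-Seq ultralow input kit, libraries were made by Nextera XT tagmentation and amplification, and sequencing was paired-end at 75 bp. These kits amplify cDNA by PCR and carry no molecular identifiers, so reads are not independent molecules, and counting intervals and floors cover counting error only. The deposited values are whole-number counts of reads per gene, made by the authors, per the submitters' processing notes, with STAR (version not given), HTSeq 0.11.2 and the mouse build GRCm38. The annotation release, the strand setting and the treatment of reads with several positions were not given in the sources used here. Genes with near-identical copies, and genes that overlap another gene, are therefore uncertain. Of the genes named in the text, 97 were looked up in the GENCODE M21 annotation of GRCm38, and 12 of these overlap another protein-coding gene. They are Alas2, Cd27, Csf1r, Fgl2, Foxp3, Gata3, Gpr34, Grn, Irf7, Itgam, Junb and P2ry12. Of 51361 gene symbols in the deposited count table, 97.2% were found in that annotation, which gave the coordinates. No row of the table lacked a gene name, and no column was left out.

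Libraries were grouped by their titles into tMCAO brain, tMCAO blood and sham blood, 2 libraries each. Totals ranged from 14348179 to 24460894 counts. The 2 libraries of each group are listed as separate samples by the labels, and each counted as a sample. Their counts differed by more than counting noise (chi-square per degree of freedom of 204 in tMCAO brain, 219 in tMCAO blood and 25.3 in sham blood). This shows only that no file repeats another, since separately amplified portions of 1 sample would also differ so. Genes were filtered with filterByExpr (minimum count 10), which left 16657, scaled by TMM, and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. All 6 libraries entered one fit with 3 residual degrees of freedom and no covariates, called the main fit in the text. P-values were adjusted by Benjamini-Hochberg within each of the 3 comparisons, with a threshold of 0.05. The standard error of a log2 change is its size divided by the square root of the F statistic. CPM in the text are scaled to the TMM-adjusted library size, and shares of counts use the raw totals with 95% Wilson intervals. A fold against a group with 0 counts is a lower bound over a floor of 3 counts in the group, and with 1 to 3 counts the ratio is given with its exact 95% interval.

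The comparisons, the tests, the list of alternatives, 35 gene lists (pathways, Treg programmes and markers of other cell types) and the rule for named genes were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 35 lists within a comparison. No list call held with an estimated correlation in any of the 3 comparisons. Fry was run as a second list test. Genes were named by 3 parts of the rule. The first part named 14 key genes in every comparison. The second named the 10 largest changes in each direction among called genes with a mean of at least 20 CPM in the higher group and no overlap between the groups, leaving out predicted genes, unnamed identifiers and variable segments of antigen receptors. The third named up to 4 called members of each list described, by smallest adjusted p, or up to 2 of the most abundant members in a list with no call. A selection of the genes so named is given in the text, and some are not reported here.

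The tests were checked on simulated counts with the means and sizes of the real libraries and 200 changed genes among 16657. Of genes changed 16-fold, 53.0% were recovered for tMCAO brain against tMCAO blood, 59.1% for tMCAO blood against sham blood and 54.5% for tMCAO brain against sham blood. Of genes changed 4-fold the recovered shares were 2.99%, 11.9% and 0%, and of genes changed 2-fold 0% in each, so 2-fold changes were not recovered in the simulation. The limit in the real data may differ, since more genes passed there than the 200 changed here. Some changes under 4-fold were called in the real data. The simulations gave 4, 6 and 1 false calls in the same order, 9.76%, 11.3% and 2.70% of all calls, where 5% is the nominal share. In the simulated list test, the list raised 2-fold was called and 0 of 20 unchanged lists were. Simulated genes were drawn independently, so this check could not show false calls that arise from correlated genes. The estimated correlation in the real T cell identity list was 0.936.

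The alternatives were DESeq2 size factors within edgeR, no filter on low counts, a stricter filter (at least 5 CPM in 2 libraries), the Wald test of DESeq2 1.42.0, limma-voom, a fit of only the 2 groups compared, the replicate number as a block, each library left out in turn, and libraries thinned to 14348179 counts. Added after the data were seen were scaling to 15 T cell identity genes, leaving out 216 marker genes of other cell types, and leaving out both tMCAO libraries numbered 1. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.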

Results

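Regulatory T cells (Tregs), the CD4-positive lymphocytes that restrain immune responses, were sorted as CD4+CD25+Foxp3+ cells from mice carrying a Foxp3-driven reporter of green fluorescent protein fused to the diphtheria toxin receptor. The mice were 9-week-old males of the C57BL/6N background. Transient middle cerebral artery occlusion (tMCAO), a model of ischaemic stroke in which a brain artery is blocked and reopened, lasted 60 min, and cells were taken 14 days later from brain and from blood. Blood Tregs of sham-operated mice served as the control. The 6 libraries, each of 500 to 1000 cells, formed 3 groups of 2: tMCAO brain, tMCAO blood and sham blood. The series title names osteopontin, the secreted protein encoded by Spp1, and an exchange between Tregs and microglia in white matter repair. Total counts were 19856348 and 24460894 in tMCAO brain, 19312572 and 16663506 in tMCAO blood, and 15216373 and 14348179 in sham blood. Of 51361 genes in the count table, 31242 had a count and 16657 were tested. The labels do not say that the 2 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

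The libraries differed in how much T cell RNA and how much RNA of other cell types they held. The 17 T cell identity genes took 0.0302% and 0.158% of all counts in tMCAO brain, 0.0713% and 0.469% in tMCAO blood, and 0.917% and 0.884% in sham blood. The 24 microglia markers took 5.26% and 4.81% of counts in tMCAO brain, 1.97% and 1.36% in tMCAO blood and 0.359% and 0.405% in sham blood. The 25 monocyte and macrophage markers took 14.4% and 6.497% in tMCAO brain against 3.96% and 2.36% in tMCAO blood and 0.853% and 0.807% in sham blood. Red cell genes took 16.3% and 18.1% of sham blood counts, 0.121% and 3.92% of tMCAO blood counts and 0.0352% and 0.0513% of tMCAO brain counts. B cell genes took 0.0505% and 1.39% of tMCAO brain counts, 0.0244% and 0.106% of tMCAO blood counts and 0.094% and 0.124% of sham blood counts. Genes of CD8 T cells and natural killer cells took 0.446% and 0.526% in tMCAO brain, 0.522% and 0.447% in tMCAO blood and 0.0835% and 0.101% in sham blood. The similar brain shares do not stand for most of these 17 genes, whose log2 ratio of brain library 2 to library 1 had a median of 3.75 (range -0.849 to 7.19). The most abundant gene was Apoe, encoding a lipid carrier of glia and macrophages, in both tMCAO brain libraries (9.86% and 4.54% of counts). It was the chemokine gene Ccl6 in tMCAO blood library 1 (2.66%) and the beta-globin gene Hbb-bs in tMCAO blood library 2 (2.09%) and in sham blood (7.44% and 7.62%). The half-widths of the 95% Wilson intervals of the list shares were at most 6.60% of the share, and they cover counting error only.

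**Figure D1:**
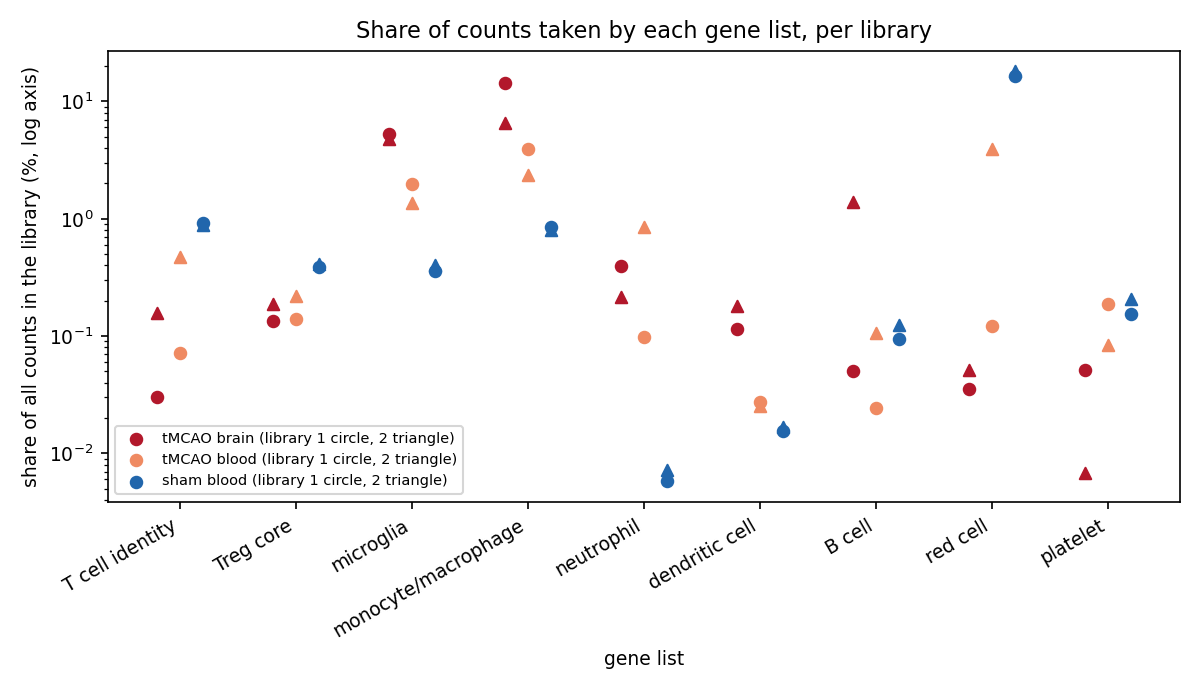
Share of all counts (%, log axis) taken by 9 gene lists in each of the 6 libraries, coloured by group, with a circle for library 1 and a triangle for library 2. T cell identity genes lie at 0.0302% and 0.158% in tMCAO brain and at 0.917% and 0.884% in sham blood, and microglia markers lie at 5.26% and 4.81% in tMCAO brain.

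The genes that define the sorted population were present in every library, at unequal levels. Foxp3 (chromosome X, 7573644 to 7595245, plus strand, GRCm38), the lineage factor of Tregs used in the sort, stood at 0.726 and 19.6 CPM in tMCAO brain, 0.538 and 5.18 CPM in tMCAO blood and 50.1 and 60.7 CPM in sham blood. Its log2 difference was 1.83 ± 1.44 (SE) for tMCAO brain against tMCAO blood (edgeR adjusted p = 0.44), and -4.27 ± 1.57 for tMCAO blood against sham blood (edgeR adjusted p = 0.135). Its annotated span overlaps Ccdc22 and Ppp1r3f, and whether counting used strand was not given in the sources used here. Il2ra, which encodes CD25, stood at 22.99 and 92.1 CPM in tMCAO brain, 20.5 and 118 CPM in tMCAO blood and 329 and 399 CPM in sham blood. Cd4 levels were 42.6 and 33.7 CPM, 12.6 and 88.1 CPM and 171 and 183 CPM in the same order, and those of the T cell receptor component Cd3e were 10.7 and 87.1 CPM, 17.2 and 119.7 CPM and 441 and 418 CPM. None of these 4 genes passed in the main edgeR fit in any of the 3 comparisons, in which their adjusted p lay between 0.125 and 0.871. Other settings did give calls. By DESeq2, Foxp3, Il2ra and Cd3e were lower in tMCAO blood than in sham blood (adjusted p = 0.00768, 0.0307 and 0.0431). Il2ra, Cd4 and Cd3e were so in tMCAO brain against sham blood (0.0137, 0.0265 and 0.013). Cd4 passed edgeR without tMCAO blood library 2 for tMCAO blood against sham blood (0.0197), and without tMCAO blood library 1 or 2 for tMCAO brain against sham blood (0.0107 and 0.00996) or with only these 2 groups fitted (0.00933). With the replicate number as a block in edgeR, Foxp3 and Il2ra passed as lower in tMCAO blood than in sham blood (0.0456 and 0.0442). Il2ra and Cd3e did so in tMCAO brain against sham blood. With no filter on low counts all 4 passed as lower in both comparisons with sham blood (highest adjusted p = 1.42e-04), and Foxp3 passed as higher in tMCAO brain than in tMCAO blood (0.0015).

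Spp1 (chromosome 5, 104435118 to 104441050, plus strand, GRCm38, protein-coding) was abundant in both tMCAO brain libraries, at 19284 and 12353 CPM, against 669 and 234 CPM in tMCAO blood and 0.257 and 5.28 CPM in sham blood. The level in tMCAO brain was 5732-fold that of sham blood (log2 change 12.48 ± 1.79, edgeR adjusted p = 0.0155), and tMCAO blood was 164-fold higher than sham blood (log2 change 7.35 ± 1.48, edgeR adjusted p = 0.0421). Between tMCAO brain and tMCAO blood the difference was 35.03-fold (log2 5.13 ± 1.32) with both brain libraries above both blood libraries, and it did not pass the edgeR test (adjusted p = 0.0742; range over 17 alternative settings 1.40e-16 to 0.297, of which 4 passed, 1 of them with a single library in each tMCAO group). The microglia markers and the monocyte and macrophage markers were also at their highest share of counts in the tMCAO brain libraries. The tMCAO blood against sham blood call was lost without tMCAO brain library 1 or 2 (adjusted p = 0.0526 and 0.0533), without tMCAO blood library 1 (0.105) and without sham blood library 1 or 2 (0.172 and 0.235, with log2 changes of 6.37 and 10.74). The tMCAO brain against sham blood call was lost without sham blood library 1 or 2 (0.0989 and 0.0926, with log2 changes of 11.51 and 15.87).

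**Figure D2:**
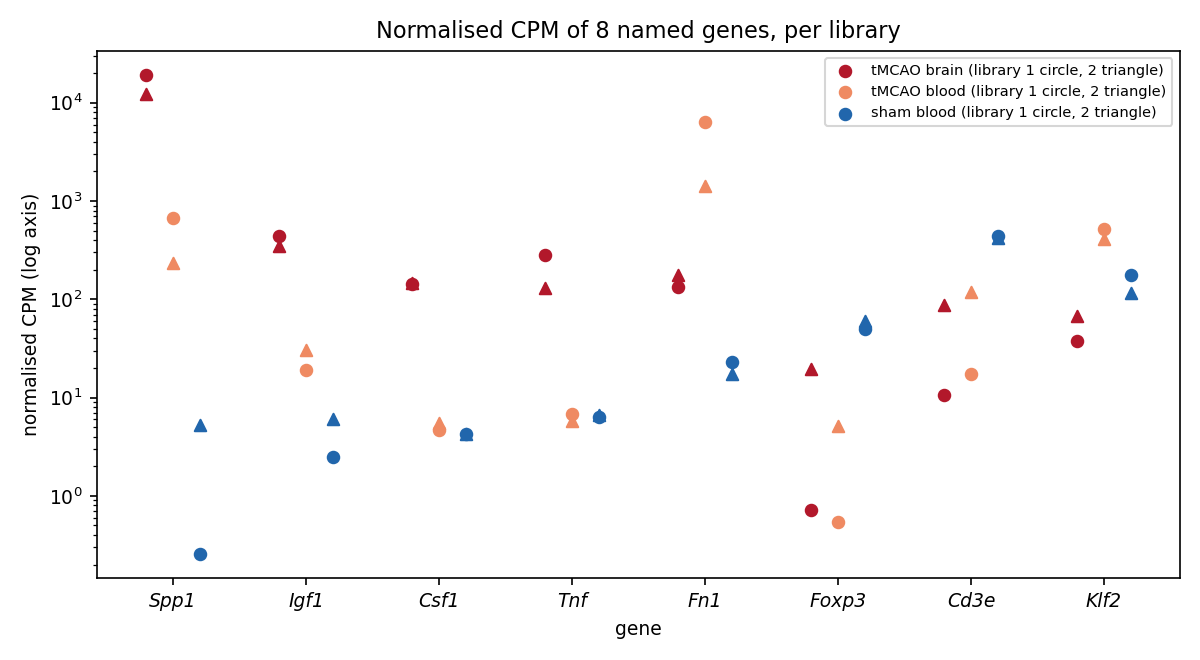
Normalised CPM (log axis) of 8 named genes in each of the 6 libraries, coloured by group, with a circle for library 1 and a triangle for library 2. Spp1 lies at 19284 and 12353 CPM in tMCAO brain and at 0.257 and 5.28 CPM in sham blood, whereas Foxp3 lies at 0.726 and 19.6 CPM in tMCAO brain and at 50.1 and 60.7 CPM in sham blood.

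Libraries sorted as Tregs from the injured brain were compared with those from blood of operated mice to ask which transcripts differed between the 2 sites. Foxp3 was under 1 CPM in library 1 of both groups, so a difference between the libraries is not shown to be one of Tregs. Growth factor and cytokine genes that rose in tMCAO brain included Csf1, encoding the macrophage growth factor M-CSF (28.2-fold, log2 change 4.82 ± 0.28, 142 and 147 CPM against 4.68 and 5.53 CPM), Igf1 (15.8-fold, 436 and 346 CPM against 19.1 and 30.4 CPM), Tnf (32.9-fold) and Osm (20.7-fold). The Csf1 call held without any 1 library and the Igf1 call was lost without each (adjusted p = 0.0552 to 0.066). Those of Tnf and Osm were lost without tMCAO blood library 2 (0.0503 and 0.0503), sham library 1 (0.0544 and 0.0544) or sham library 2 (0.0548 and 0.0552). Areg (chromosome 5, 91139599 to 91148432, GRCm38), encoding the epidermal growth factor receptor ligand amphiregulin, stood at 8.89 and 38.4 CPM in tMCAO brain and at 3 counts over both tMCAO blood libraries, a ratio of 341-fold (95% counting interval 117 to 1658) (edgeR adjusted p = 0.0334). The Areg call was lost by limma-voom (adjusted p = 0.0883) and with only the 2 groups compared (0.0839). It was also lost without brain library 2 (0.0784), tMCAO blood library 1 or 2 (0.0646 and 0.0767) or sham library 1 or 2 (0.0849 and 0.0831). Klf2, a transcription factor gene of lymphocyte recirculation, was 8.78-fold lower in brain, a call lost without each single library (adjusted p = 0.0542 to 0.0721). The Klf2 call was also lost by edgeR with only the 2 groups compared (adjusted p = 0.0719) and scaled to T cell genes (0.734). In all, 816 genes passed the edgeR quasi-likelihood test at an adjusted p under 0.05, 588 higher and 228 lower in brain. With libraries scaled to T cell genes, a setting chosen after results were seen, it was 374 higher and 31 lower.

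Single genes with the largest changes between the 2 sites went both ways. Il12b, encoding the p40 subunit of interleukin-12, was at least 2813-fold higher, Fscn1, an actin-bundling protein of mature dendritic cells, at least 1535-fold higher, and Sall1, a transcription factor of microglia, at least 393-fold higher, each with 0 counts in tMCAO blood and bounded by a floor of 3 counts over the group. Tspan7 was at least 1169.7-fold higher by the same floor, and Sparc 10838-fold (95% counting interval 3708 to 52559) higher. In the other direction Retnla, a gene of alternatively activated macrophages, was at least 15902-fold lower in brain, where it had 0 counts, and Arg1, which encodes arginase 1, was 522-fold lower. The globin gene Hba-a2 was at least 25477-fold lower and Hbb-bs 46002-fold lower, both with near-identical copies (Hba-a1, Hbb-bt) that could share reads. The platelet chemokine gene Ppbp was 629.7-fold lower.

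Genes of stimulus-induced transcription were among those that rose in brain. Any difference in how cells were prepared from the 2 tissues cannot be told apart from site in this design. Of 30 immediate early genes, transcribed within minutes of a stimulus, 12 rose and none fell (23 rose when adjusted over the list alone). The immediate early list had a camera adjusted p = 6.61e-09, and adjusted p = 0.378 with an estimated correlation. Those that rose included Egr1 (47.8-fold), Fosb (133-fold), Btg2 (13.2-fold) and Junb (17.03-fold). Of 27 genes of NF-kB and TNF signalling 11 rose and none fell (15 adjusted over the list alone; camera adjusted p = 1.01e-07, and adjusted p = 0.311 with an estimated correlation), with Nfkbid (21.5-fold) and Nfkbiz (13.6-fold) among them. Of 37 secreted factors 7 rose, and 1 fell, Fn1, named after its value was seen (21 and 2 adjusted over the list alone). The secreted factor list had a camera adjusted p = 2.60e-05, and adjusted p = 0.311 with an estimated correlation. Of 20 activation and checkpoint genes 6 rose, such as Cd83 (636-fold), Lag3 (157-fold) and Nr4a2 (44.5-fold) and the nuclear receptor gene Nr4a3 (95.05 and 169.8 CPM against 0.323 and 0 CPM), and 1 fell, Cd44, named after its value was seen. The list as a whole did not pass camera (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0611, and adjusted p = 0.705 with an estimated correlation), but did without brain library 1 (camera adjusted p = 0.0116) or tMCAO blood library 2 (0.0387), and it passed by fry (adjusted p = 0.0308). Beside these groups, microglia markers took 5.26% and 4.81% of counts in tMCAO brain and 1.97% and 1.36% in tMCAO blood, and Csf1, Tnf, Igf1, Cd83 and the immediate early genes are also transcribed by microglia.

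Of 20 recirculation and resting genes 4 fell in brain and none rose, including Klf2 (log2 change -3.13 ± 0.43), Klf3 (-1.60 ± 0.33) and Ly6c1 (0 and 0.572 CPM against 22.3 and 56.6 CPM). The Klf3 call was lost without each single library (adjusted p = 0.0713 to 0.144), and that of Ly6c1 without brain library 1 (0.0504), tMCAO blood library 2 (0.0595) or sham library 1 or 2 (0.0852 and 0.0831). Adjusted over the list alone, 5 fell and 2 rose (camera adjusted p = 0.0611, and adjusted p = 0.891 with an estimated correlation), and the list passed without brain library 2 (camera adjusted p = 0.00395) or tMCAO blood library 1 (0.00334). Of 20 genes of tissue Tregs, Areg and Ccr8 rose, Ccr8, a chemokine receptor, by 64.02-fold (5.08 and 29.3 CPM against 0.431 and 0.0997 CPM), and none fell (3 higher adjusted over the list alone). The tissue Treg list had a camera adjusted p = 0.684, and adjusted p = 0.971 with an estimated correlation. The Ccr8 call was lost without brain library 2 (adjusted p = 0.0939), tMCAO blood library 1 or 2 (0.0831 and 0.118) or sham library 1 or 2 (0.105 and 0.104). The interleukin-33 receptor gene Il1rl1 stood at 2.18 and 19.9 CPM in brain and 12.3 and 34.2 CPM in blood, and Gata3 at 1.69 and 43.95 CPM and 14.4 and 79.4 CPM, with adjusted p of 0.496 and 0.643 by edgeR. Il10, encoding the anti-inflammatory interleukin-10, stood at 84.1 and 20.6 CPM in brain and 0.0538 and 1.15 CPM in blood (edgeR adjusted p = 0.0635), and Tgfb1 at 20.3 and 24.9999 CPM and 3.28 and 9.72 CPM (edgeR adjusted p = 0.109). Of 19 Treg core genes, Swap70 (3.11-fold) and Il10ra (2.75-fold), which are also transcribed by B and myeloid cells, rose, and none fell (3 higher adjusted over the list alone). The median log2 change of this list was -0.19 whereas camera gave an upward direction (camera adjusted p = 0.876, and adjusted p = 0.977 with an estimated correlation). Ctla4 and Ikzf2, a checkpoint receptor and a transcription factor of Tregs, stood at 12.2 and 148 CPM and 20.2 and 62.4 CPM in brain against 29.4 and 97.7 CPM and 64.4 and 437 CPM in blood (edgeR adjusted p = 0.865 and 0.142). By DESeq2 Ikzf2, Il10 and Tgfb1 passed (adjusted p = 0.0192, 0.014 and 0.029). No T cell identity gene passed in the main edgeR fit, over all genes or adjusted over the list alone (camera adjusted p = 0.0555, and adjusted p = 0.891 with an estimated correlation), and the list passed downward without brain library 2 (camera adjusted p = 8.45e-04) or tMCAO blood library 1 (1.43e-04). Cd3d, a subunit of the T cell receptor complex, stood at 34.3 and 139 CPM in brain and 122 and 524 CPM in blood, and Trbc2 at 23.8 and 147 CPM and 85.2 and 596 CPM.

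**Figure D3:**
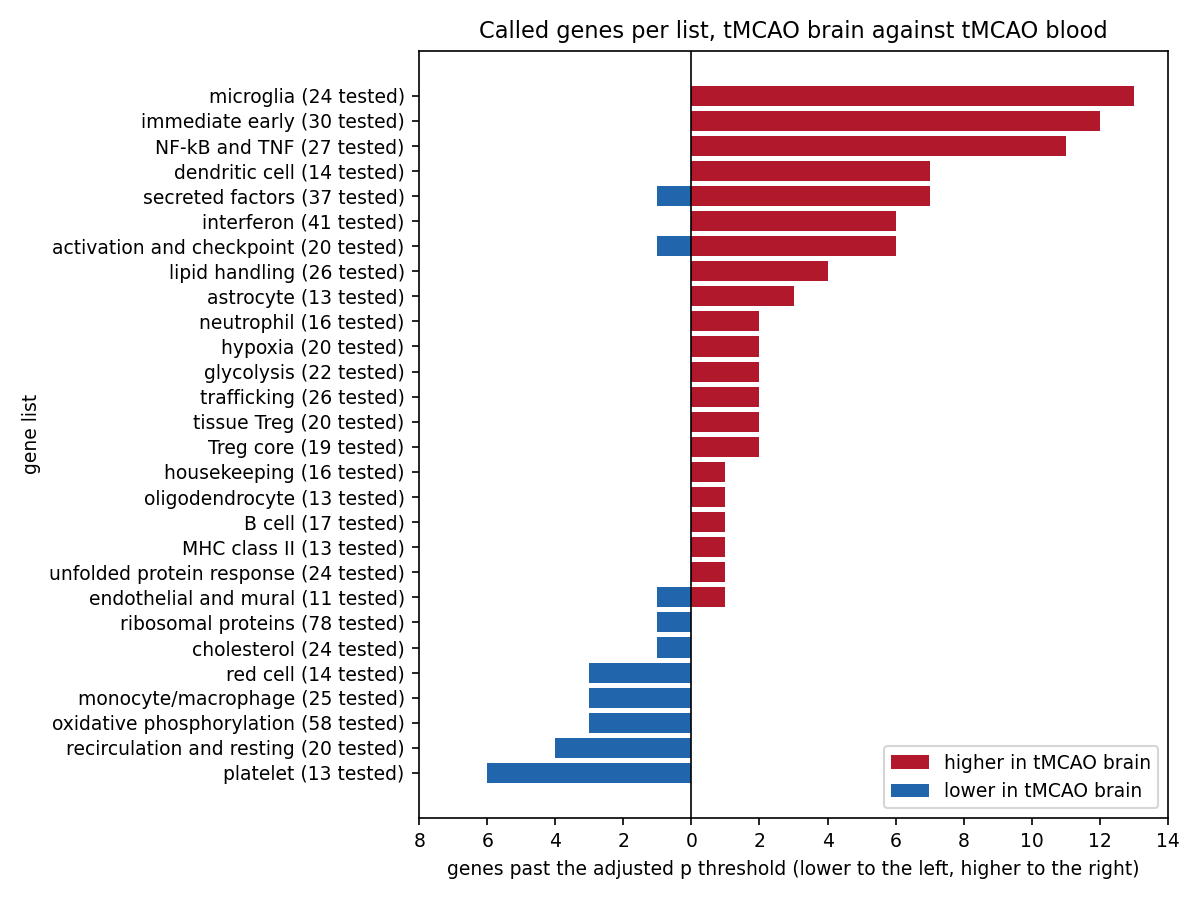
Number of genes past the edgeR threshold in each fixed list with at least 1 call, for tMCAO brain against tMCAO blood (x axis, genes; higher in brain to the right, lower to the left; number tested in brackets). The microglia list has 13 genes higher, the immediate early list 12, and the platelet list 6 lower.

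Markers of other cell types also separated brain from blood. Of 24 microglia markers 13 rose in brain and none fell (21 adjusted over the list alone; camera adjusted p = 1.22e-12, and adjusted p = 0.311 with an estimated correlation), among them Gpr34 (93.8-fold) and P2ry12 (22.6-fold). Of 14 dendritic cell markers 7 rose (11 adjusted over the list alone; camera adjusted p = 1.48e-05, and adjusted p = 0.378 with an estimated correlation), including Siglech (80.5-fold) and Flt3 (54.1-fold). Of these 14 markers 4 also stand in another list, so the list is not specific to dendritic cells. Of the monocyte and macrophage markers, Lyz1 (10.9-fold), Chil3 (149-fold) and Plac8 (6.55-fold) fell, 3 of 25 tested (5 higher and 4 lower adjusted over the list alone). The monocyte and macrophage list had a camera adjusted p = 0.958, and adjusted p = 0.988 with an estimated correlation. Of 13 platelet genes 6 fell (10 adjusted over the list alone; camera adjusted p = 1.65e-07, and adjusted p = 0.311 with an estimated correlation), and of 14 red cell genes 3, all of them globins (8 adjusted over the list alone). The red cell list had a camera adjusted p = 4.41e-04, and adjusted p = 0.797 with an estimated correlation. Among 41 interferon-stimulated genes 6 rose, such as Isg15 (22.6-fold) and Irf7 (3.94-fold) (9 higher and 1 lower adjusted over the list alone). The interferon list had a camera adjusted p = 0.403, and adjusted p = 0.971 with an estimated correlation (camera adjusted p = 0.00328 without brain library 2). The cholesterol exporters Abca1 (5.204-fold) and Abcg1 (3.86-fold) were among 4 of 26 lipid handling genes that rose (10 higher and 5 lower adjusted over the list alone). The lipid handling list had a camera adjusted p = 0.145, and adjusted p = 0.797 with an estimated correlation. Of 78 ribosomal protein genes, 77 had a negative log2 change and Rpl38 fell (3.62-fold; 38 lower adjusted over the list alone). The ribosomal list had a camera adjusted p = 2.56e-15, and adjusted p = 0.705 with an estimated correlation. Of 58 oxidative phosphorylation genes 3 fell, one being Ndufa4 (2.89-fold; 1 higher and 33 lower adjusted over the list alone). The oxidative phosphorylation list had a camera adjusted p = 2.78e-07, and adjusted p = 0.797 with an estimated correlation.

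Of 38 cell cycle genes none passed by edgeR (0 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.00494, and adjusted p = 0.891 with an estimated correlation), and the downward list call was lost without brain library 1 (camera adjusted p = 0.834) or tMCAO blood library 2 (0.325). Pcna, a clamp of DNA polymerase, stood at 108 and 124 CPM in brain and 118 and 153 CPM in blood. The co-stimulatory gene Cd86 was 6.72-fold higher in brain, and Clu, which encodes clusterin and is transcribed by astrocytes, 7.53-fold higher. Calls higher and lower in the remaining lists described were 2 and 0 for glycolysis (2 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0611, and adjusted p = 0.797 with an estimated correlation; camera adjusted p = 0.00334 without tMCAO blood library 1). They were 1 and 0 for MHC class II presentation (3 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0032, and adjusted p = 0.705 with an estimated correlation). Those of the unfolded protein response numbered 1 and 0 (6 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.00412, and adjusted p = 0.864 with an estimated correlation; camera adjusted p = 0.203 without tMCAO blood library 2). For astrocyte markers they were 3 and 0 (10 higher and 0 lower adjusted over the list alone; camera adjusted p = 3.37e-07, and adjusted p = 0.378 with an estimated correlation). For oligodendrocyte markers they were 1 and 0 (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0021, and adjusted p = 0.705 with an estimated correlation). The red cell, ribosomal, oxidative phosphorylation, cell cycle, MHC class II and unfolded protein response lists did not pass by fry (adjusted p = 0.238, 0.0559, 0.0931, 0.649, 0.1 and 0.191).

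The number of calls between brain and blood of operated mice changed with the libraries fitted. Sham libraries enter this fit through the shared estimate of spread. Leaving out libraries also lowers the residual degrees of freedom, and these causes were not told apart. With the 4 libraries compared fitted alone 26 genes passed by edgeR, and leaving out 1 library gave 175 genes (without brain library 1), 108 (brain library 2), 273 (tMCAO blood library 1), 177 (tMCAO blood library 2), 30 (sham library 1) and 30 (sham library 2). DESeq2 on all 6 libraries gave 3451.

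The second comparison asked what differed between libraries sorted as blood Tregs from operated and from sham mice. Genes that rose after tMCAO included ones transcribed by monocytes, macrophages and neutrophils. Fn1, encoding fibronectin, was 192-fold higher (log2 change 7.58 ± 0.91, 6349.9 and 1434 CPM against 23.2 and 17.4 CPM), Itgam, the CD11b integrin subunit, 60.2-fold, the monocyte receptor gene Cd14 43.6-fold, and Lyz1 95.2-fold. Genes that fell included ones of red cells and platelets and the interferon-stimulated gene Isg15 (17.3-fold). In total 1246 genes passed the edgeR test, 722 higher and 524 lower in tMCAO blood, and with libraries scaled to T cell genes 1248 higher and 1 lower.

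The genes with the largest changes that rose included Retnla (at least 11552-fold), Wfdc21 (at least 2207-fold) and Lcn2, an iron-sequestering protein of neutrophils (at least 924-fold), all with 0 counts in sham blood and bounded by a floor of 3 counts over the group. S100a8, encoding a subunit of calprotectin, stood at 199 and 3466 CPM after tMCAO and 0.0642 and 0.704 CPM in sham blood. Those that fell included Epb42, a red cell membrane protein (319.95-fold), the platelet tubulin gene Tubb1 (200.4-fold), Fech, encoding the last enzyme of haem synthesis (31.9-fold), and Isg20 (27.8-fold).

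Of 25 monocyte and macrophage markers 10 rose in tMCAO blood and none fell, and all 25 had a positive log2 change (18 rose adjusted over the list alone). The monocyte and macrophage list had a camera adjusted p = 8.75e-08, and adjusted p = 0.885 with an estimated correlation. Of 16 neutrophil markers 3 rose, Lcn2, Wfdc21 and S100a8 (7 adjusted over the list alone; camera adjusted p = 9.11e-04, and adjusted p = 0.885 with an estimated correlation), and the neutrophil share of counts was 0.0981% and 0.847% after tMCAO against 0.0058% and 0.00716% in sham blood. Of 24 microglia markers 7 rose, such as the complement gene C1qc (41.4-fold), Csf1r (4.32-fold) and Aif1 (8.18-fold), which blood monocytes or macrophages also transcribe, and 3 fell: Gpr34 (8.49-fold), Selplg (3.403-fold) and P2ry12, the last named after its value was seen (10 higher and 3 lower adjusted over the list alone). Platelet and T cell genes also stood lower in tMCAO blood, and which cells gave the falls of Gpr34, Selplg and P2ry12 was not tested. The microglia list had a camera adjusted p = 0.0645, and adjusted p = 0.885 with an estimated correlation (camera adjusted p = 0.00148 without sham blood library 2). Secreted factors rose in 5 of 37 cases, namely Spp1, Fn1, Fgl2 (2.92-fold), Grn (11.1-fold) and Igf1 (5.79-fold), beside the higher monocyte share (5 adjusted over the list alone). The secreted factor list had a camera adjusted p = 0.204, and adjusted p = 0.885 with an estimated correlation. Lpl and Abca1, genes of lipid uptake and export, rose 22.8-fold and 10.7-fold. The adhesion receptor gene Cd44 rose 5.92-fold and the transcription factor gene Klf4 5.77-fold, while Cd83 fell 8.63-fold and Irf7 3.39-fold. Of 41 interferon-stimulated genes 3 fell and none rose, while 23 had a positive and 18 a negative log2 change (5 lower adjusted over the list alone). As a whole the interferon list did not pass (camera adjusted p = 0.707, and adjusted p = 0.944 with an estimated correlation). Of 58 oxidative phosphorylation genes 3 rose, among them Ndufc1 (4.1004-fold) and Cox7c (3.06-fold) (25 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00149, and adjusted p = 0.944 with an estimated correlation); without tMCAO blood library 1 the adjusted p of the list was 0.0664.

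T cell genes were at lower levels in tMCAO blood than in sham blood, without a call in the main edgeR fit. Other settings gave the calls described with the sort genes above. Of 17 T cell identity genes 16 had a negative log2 change, none passed by edgeR over all genes or adjusted over the list alone, and the list passed camera with the preset correlation (adjusted p = 4.91e-04, and adjusted p = 0.944 with an estimated correlation). The tyrosine kinase gene Lck stood at 59.6 and 326 CPM after tMCAO and 1147 and 1342 CPM in sham blood, and the receptor gene Trbc2, which has the near-identical copy Trbc1, at 85.2 and 596 CPM and 1156 and 937 CPM. Among the Treg core genes there were 15 of 19 log2 changes below 0 and no call in the main edgeR fit, over all genes or adjusted over the list alone (camera adjusted p = 0.00528, and adjusted p = 0.885 with an estimated correlation; camera adjusted p = 0.0602 without tMCAO blood library 1). The folate receptor family gene Izumo1r, for instance, stood at 11.9 and 95.2 CPM and 496 and 604 CPM. Ctla4 levels were 29.4 and 97.7 CPM after tMCAO and 251 and 271 CPM in sham blood, and Ikzf2 levels 64.4 and 437 CPM and 582 and 509.6 CPM. Of 20 recirculation genes Igfbp4 fell (15.6-fold), and the list passed camera downward (1 higher and 5 lower adjusted over the list alone). The recirculation list had a camera adjusted p = 9.11e-04, and adjusted p = 0.885 with an estimated correlation. Klf2 did not pass, at 519 and 409.6 CPM against 175 and 116 CPM in sham blood (edgeR adjusted p = 0.0582), but did by DESeq2 (0.00122), limma-voom (0.049), with a stricter filter (0.042) and with only the 2 groups compared (0.0444). Areg had 3 counts over both tMCAO blood libraries against 2.57 and 1.55 CPM in sham blood (adjusted p = 0.0721 by edgeR and 0.00143 by DESeq2). Il10 had 0 counts in sham blood and 0.0538 and 1.15 CPM after tMCAO (edgeR adjusted p = 0.195). Il1rl1, Gata3 and Tgfb1 had log2 differences of -1.09 ± 0.95, -0.82 ± 1.33 and -0.03 ± 0.57 (edgeR adjusted p = 0.474, 0.709 and 0.986). Of 14 red cell genes 3 fell, Epb42, Fech and Ube2l6 (18.7-fold), with 7 adjusted over the list alone (camera adjusted p = 2.13e-07, and adjusted p = 0.885 with an estimated correlation), and of 13 platelet genes 6 fell, such as Ppbp (8.12-fold), with 11 adjusted over the list alone (camera adjusted p = 3.05e-07, and adjusted p = 0.885 with an estimated correlation). No list passed by fry in this comparison (lowest adjusted p = 0.0631).

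No gene passed the edgeR test in this comparison without tMCAO blood library 1, without sham blood library 1 or without sham blood library 2, where 4003, 3260 and 2572 genes had an unadjusted p under 0.05. Limma-voom called 524 genes higher and 622 lower, against 722 and 524 by edgeR.

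The third comparison, tMCAO brain against sham blood, differs in both site and operation, and it shares its libraries with the other 2 comparisons. Among the secreted factor genes that rose in brain, Igf1 was 91.5-fold higher (log2 change 6.52 ± 0.59, 436 and 346 CPM against 2.503 and 6.05 CPM), Csf1 34.1-fold, Tnf 32.03-fold, and Vegfa, the vascular endothelial growth factor gene, 969-fold (95% counting interval 268 to 8006) with 2 counts in sham blood. Il10, with 0 counts in sham blood, was at least 459-fold higher at 84.1 and 20.6 CPM (edgeR adjusted p = 0.0302). The Il10 call was lost by limma-voom (0.0686), without brain library 1 (0.0802) and without sham library 1 or 2 (0.151 and 0.149). By edgeR 1772 genes passed, 1335 higher and 437 lower in brain, and with libraries scaled to T cell genes 9206 higher and 56 lower.

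Among the genes with the largest changes, Ccl8 was at least 13532-fold and Ccl22 at least 1569.9-fold higher over a floor of 3 counts in the sham group. In the other direction the red cell gene Alas2 was 120173-fold (95% counting interval 33267 to 992314) lower and Hbb-bs had a log2 change of -18.55 ± 2.87. Of 37 secreted factors 18 rose (26 higher and 4 lower adjusted over the list alone). The secreted factor list had a camera adjusted p = 6.78e-07, and adjusted p = 0.251 with an estimated correlation. Of 30 immediate early genes 21 rose, such as Egr1 (146-fold) and Atf3 (421-fold) (22 adjusted over the list alone). The immediate early list had a camera adjusted p = 4.67e-09, and adjusted p = 0.445 with an estimated correlation. NF-kB and TNF genes rose in 13 of 27 cases (16 higher and 2 lower adjusted over the list alone). The NF-kB and TNF list had a camera adjusted p = 1.02e-04, and adjusted p = 0.445 with an estimated correlation. Microglia markers rose in 23 of 24 cases, including Trem2 (136-fold) and Fcrls (8975-fold), with 23 adjusted over the list alone (camera adjusted p = 9.71e-15, and adjusted p = 0.251 with an estimated correlation). Monocyte and macrophage markers rose in 13 of 25 cases, such as Cd14 (333-fold), with 20 higher and 1 lower adjusted over the list alone (camera adjusted p = 6.78e-07, and adjusted p = 0.52 with an estimated correlation). Of 14 red cell genes 11 fell (12 adjusted over the list alone; camera adjusted p = 1.44e-11, and adjusted p = 0.461 with an estimated correlation), and of 13 platelet genes 11 (12 adjusted over the list alone). The platelet list had a camera adjusted p = 2.91e-12, and adjusted p = 0.251 with an estimated correlation. The co-stimulatory gene Cd86, the checkpoint gene Lag3 and the lipid exporter gene Abca1 rose 11.1-fold, 78.1-fold and 55.6-fold. Since microglia and monocyte markers rose in the same libraries, these rises are not shown to be ones of Tregs.

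Of 19 Treg core genes 2 fell against sham blood, Gpr83 (307-fold) and Izumo1r (43.3-fold), and 3 rose, Il10ra (3.02-fold), the ectonucleotidase gene Entpd1 (6.06-fold) and Swap70, the last named after its value was seen (4 lower and 3 higher adjusted over the list alone). Il10ra, Entpd1 and Swap70 are also transcribed by myeloid cells, so their rises are not shown to be ones of Tregs. The Treg core list had a camera adjusted p = 0.0197, and adjusted p = 0.576 with an estimated correlation. The camera adjusted p of this list was 0.139 without tMCAO brain library 1 and 0.0502 without sham blood library 2. All 17 T cell identity genes had negative log2 changes. None passed in the main edgeR fit over all genes, whereas Cd3e and Cd4 did by DESeq2 (0.013 and 0.0265) and by edgeR with no filter (3.05e-11 and 1.15e-06), and 14 passed adjusted over the list alone (camera adjusted p = 6.76e-07, and adjusted p = 0.52 with an estimated correlation); Lck, for example, stood at 43.1 and 237 CPM against 1147 and 1342 CPM. Of 20 recirculation genes 4 fell, including Ly6c1 (867-fold) and Cd27 (15.6-fold), with 10 adjusted over the list alone (camera adjusted p = 6.76e-07, and adjusted p = 0.52 with an estimated correlation). The T cell identity, Treg core and recirculation lists did not pass by fry (adjusted p = 0.123, 0.271 and 0.0658). The tissue Treg factor gene Nfil3 rose 16.7-fold and Batf fell 2.88-fold. Which cells gave these changes was not tested. Of 20 tissue Treg genes 2 rose and 1 fell (camera adjusted p = 0.966, and adjusted p = 0.99 with an estimated correlation). Areg stood at 8.89 and 38.4 CPM in brain and 2.57 and 1.55 CPM in sham blood (edgeR adjusted p = 0.0727). Ctla4, Ikzf2, Il1rl1, Gata3, Klf2 and Tgfb1 had log2 differences of -1.71 ± 1.09, -3.72 ± 1.00, -2.16 ± 0.98, -1.86 ± 1.36, -1.46 ± 0.40 and 1.77 ± 0.58 (SE), none past the edgeR threshold (adjusted p = 0.347, 0.0647, 0.2, 0.413, 0.0692 and 0.1). Other settings gave calls. Areg, Ikzf2, Klf2 and Tgfb1 passed by DESeq2 (adjusted p = 0.00159, 2.13e-04, 0.00352 and 0.0337), and Areg, Ikzf2 and Tgfb1 with only the 2 groups compared (0.0479, 0.021 and 0.035). The replicate block gave a call for Ikzf2. Ikzf2 also passed by limma-voom (0.0473), and without tMCAO blood library 1 or 2 (0.024 and 0.0226), as did Tgfb1 (0.0377 and 0.0413). Il1rl1 passed without brain library 2 (0.0422), and all 7 with no filter on low counts (highest adjusted p = 0.0131). No gene passed without either sham library (edgeR; 3242 and 3075 genes had an unadjusted p under 0.05), and 621 passed without brain library 1 and 1080 without brain library 2.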

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

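Among the settings below, scaling to T cell genes, leaving out marker genes of other cell types and leaving out both tMCAO libraries numbered 1 were chosen only after results were seen. For tMCAO brain against tMCAO blood, tMCAO blood against sham blood and tMCAO brain against sham blood, in that order, edgeR gave 816, 1246 and 1772 genes. Without a filter on low counts there were 3598, 3611 and 4458, and by DESeq2 3451, 3804 and 4007. Without both tMCAO libraries numbered 1 there were 2932, 3577 and 4242, but each tMCAO group is then 1 library and the spread is that of the sham pair alone, so they are given as counts only. The first comparison gave 1237 with a stricter filter, 1446 by limma-voom and 26 with only the 2 groups compared, and the third 2752 with only the 2 groups compared. Scaled to T cell genes the 3 gave 405, 1249 and 9262, of which 31, 1 and 56 were lower, against 228, 524 and 437 by TMM. The median log2 change of all genes was then 1.22, 2.95 and 4.103, against 0.0622, 0.112 and 0.093 by TMM, and single genes are given relative to the scaled medians. Adjusted p in that setting, and the calls lost by it, belong to the change before these medians were subtracted. Leaving out 1 library at a time gave 30 to 273, 0 to 1455 and 0 to 2407 genes by edgeR, with the lone library of a group assumed to vary like the others. The lists called by camera numbered 14, 8 and 20, with an estimated correlation 0, 0 and 0, and by fry 10, 0 and 14. Leaving out 1 library gave 13 to 18, 8 to 11 and 19 to 23 lists.

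With the replicate number as a block, 803, 1318 and 1977 genes passed by edgeR, of which 645, 1011 and 1560 were also called without the block. With the block Foxp3 and Il2ra passed as lower in tMCAO blood than in sham blood (adjusted p = 0.0456 and 0.0442), and Il2ra, Cd3e and Ikzf2 as lower in tMCAO brain than in sham blood (0.0288, 0.0374 and 0.0252). Of 146 results for single genes in the text, 8 calls were gained with the block and 6 were lost. In tMCAO brain against tMCAO blood 4 gene calls were lost. In that comparison 2 gene lists in the text passed camera only once the block was added to the main setting. As a check of pairing, the deviations of equally numbered libraries from their group means correlated at r = 0.304 between brain and tMCAO blood, -0.028 between brain and sham blood and -0.070 between tMCAO blood and sham blood, and the labels do not say what a shared number means.

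Signs turned for genes that had not been called. In tMCAO brain against tMCAO blood the log2 change of Foxp3 was -1.97 without brain library 2. Il2ra and Cd3e stood at 0.34 and 0.28 without brain library 1. Without tMCAO blood library 2 the values were 1.51 for Il2ra, 1.62 for Cd4, 1.53 for Cd3e, 0.69 for Gata3 and 0.0259 for Trbc2. Cd4 was at 0.16 by limma-voom and 0.67 scaled to T cell genes. Ctla4 was at -0.29 by limma-voom, -0.0676 with the replicate block, -2.39 without brain library 2, -0.29 without tMCAO blood library 1 and -0.24 scaled to T cell genes. The Cd4 and Ctla4 values scaled to T cell genes are relative to the median log2 change of all genes in that setting, 1.22. Before that median was subtracted both were above 0. The turn of Ctla4 in that setting therefore comes from the subtraction, whereas Cd4 turned with or without it. In tMCAO blood against sham blood Tgfb1 was at 0.0173 with the stricter filter, 0.0219 without brain library 1, 0.55 without tMCAO blood library 1, 0.20 without sham blood library 2, 0.0234 after thinning and 0.60 without both tMCAO libraries numbered 1. Over the libraries left out in turn, the ranges in tMCAO brain against tMCAO blood were -1.97 to 4.25 for Foxp3, -1.59 to 1.51 for Il2ra, -1.21 to 1.62 for Cd4, -2.68 to 1.53 for Cd3e, -2.39 to 1.46 for Ctla4, -4.79 to 0.69 for Gata3 and -3.84 to 0.0259 for Trbc2. The range of Tgfb1 in tMCAO blood against sham blood was -1.07 to 0.55.

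In tMCAO brain against tMCAO blood, 5 uncalled lists turned direction, here with their camera adjusted p. Without brain library 1 these were interferon (0.434) and monocyte and macrophage (0.111). Without brain library 2 they were Treg core (0.385) and tissue Treg (0.608), and without tMCAO blood library 1 also Treg core (0.434) and tissue Treg (0.988). Without tMCAO blood library 2 they were T cell identity (0.941) and monocyte and macrophage (0.325). Treg core turned with the replicate block (0.945), and without both tMCAO libraries numbered 1 Treg core (0.924), interferon (0.411) and monocyte and macrophage (0.704) did. Over the libraries left out, their adjusted p ranged over 1.43e-04 to 0.941 for T cell identity, 0.161 to 0.894 for Treg core, 0.178 to 0.988 for tissue Treg, 0.00328 to 0.491 for interferon and 0.111 to 0.913 for monocyte and macrophage markers.

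Of 146 results for single genes in the text, 127 had the same direction and side of the threshold by DESeq2. The other 19 were called by DESeq2 but not by the main edgeR fit. Some of the 146 were not called by the main fit, so the lost calls below are larger shares of the calls. With only the 2 groups compared 39 calls were lost, and scaled to T cell genes 52. By limma-voom 18 calls were lost, and without sham blood library 1 or 2 97 and 97. Leaving out marker genes of other cell types changed none of the 108 results it could be run on. It dropped only those genes and left any other RNA of such cells in place, so it cannot exclude that RNA.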

Other observations

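The tests of explanations below were chosen only after the results were seen. Relative to T cell transcripts most genes stand higher in the brain libraries, which hold much myeloid RNA, with a median log2 change over all genes of 1.22 against tMCAO blood and 4.103 against sham blood. Per 1000 counts of 15 T cell identity genes, the co-stimulatory receptor gene Tnfrsf9 had 92.5 and 71.1 counts in the brain libraries, 7.76 and 2.53 in tMCAO blood and 4.82 and 7.13 in sham blood. Tnfrsf4, encoding OX40, had 205 and 111, 35.4 and 26.7 and 44.5 and 46.8, and the proenkephalin gene Penk 27.9 and 30.8, 0.31 and 0.722 and 1.24 and 0.219. Il2ra had 73.2 and 61.2, 29.6 and 32.95 and 37.9 and 45.9. For Foxp3 the values were 2.31 and 13.04, 0.776 and 1.44 and 5.77 and 6.996. Both brain libraries did not stand above both tMCAO blood libraries for Ikzf2, Klrg1, Gata3 and Ctla4. Ikzf2 had 64.3 and 41.5, 92.9 and 122 and 67.1 and 58.7, Klrg1 21.96 and 24.3, 23.3 and 21.7 and 25.4 and 18.3, Gata3 5.39 and 29.2, 20.8 and 22.1 and 11.4 and 7.77, and Ctla4 38.7 and 98.1, 42.4 and 27.2 and 28.9 and 31.2. These ratios were not tested, and Tnfrsf9, Tnfrsf4, Penk and Klrg1 were chosen after their values were seen.

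Spp1 was high in both brain libraries. RNA of microglia and macrophages may be a source, since the median over the microglia list was 850 and 858 CPM in the brain libraries. The sort on CD4, CD25 and Foxp3 was meant to leave out such cells. Their markers still took more counts than T cell identity genes in both brain libraries. Of the 24 microglia markers 15 reached 10 CPM in sham blood and 7 stand in another list, and the most abundant in brain were Cst3 (12789.8 and 12742 CPM) and Ctss (13178 and 8483 CPM). T cells as its only source, at one level per T cell, are argued against by the log2 ratio of brain library 2 to library 1, which was -0.64 for Spp1 and -0.335 to 3.296 over all 17 T cell identity genes. Per 1000 counts of 15 T cell identity genes Spp1 had 61404 and 8215 counts, though the ratios of Treg core genes reached down to -0.963 with Capg, Entpd1 and Nrp1, which myeloid cells also transcribe, and T cells as part of the source stay open.

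T cell and Treg core lists were lower in tMCAO blood than in sham blood by camera at the preset correlation, the latter not without tMCAO blood library 1 (adjusted p = 0.0602), and neither with an estimated correlation (0.944 and 0.885) or by fry (0.432 and 0.295), and no gene of either passed in the main edgeR fit. Lower depth is argued against by the totals, since the lower tMCAO blood total was 1.095 times the higher sham blood total. RNA of monocytes and neutrophils may contribute, since the median log2 change of the monocyte and macrophage list was 3.02, although 18 of its 25 genes reached 10 CPM in sham blood and 3 stand in another list. The sort was meant to leave out such cells, but the markers of this list took 3.96% and 2.36% of tMCAO blood counts. The medians of the Treg core and T cell lists differed by -0.12, with an interval of -0.80 to 1.20 from a bootstrap over genes. It took genes as independent, and the Treg core list holds genes that myeloid cells also transcribe. A loss of Treg core transcripts beyond that of T cell transcripts thus cannot be told apart from an equal loss by this interval. Relative to T cell identity counts, scaled as above, Foxp3 stood at 0.776 and 1.44 in tMCAO blood and 5.77 and 6.996 in sham blood. Il2ra was also lower in both tMCAO blood libraries, Ikzf2 was higher in both, and the Ctla4 values overlapped. These ratios were not tested. An effect of the operation on blood Tregs stays open and untested.

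Areg and Ccr8 were higher in brain than in tMCAO blood. RNA of microglia and macrophages at one level per cell is argued against by the log2 ratio of brain library 2 to library 1, at least 2.05 for the 2 genes and -6.51 to 1.32 over markers of both cell types. T cells cannot be told apart from B cells or dendritic cells as the source by this ratio. The sort was meant to leave out the latter 2, but their markers took counts in both brain libraries. The higher ratio, 2.42, lies inside the range of T cell identity genes (-0.335 to 3.296), and inside that of B cell and dendritic markers (-1.19 to 10.6, median 2.32). Both ratios, 2.05 and 2.42, also lie inside the range of genes of CD8 T cells and natural killer cells (-0.849 to 7.19). They lie inside that of oligodendrocyte markers as well (-2.22 to 5.70). Both the site and the shares of RNA of other cell types differed between the brain and tMCAO blood libraries. Which of them accounts for the higher Areg and Ccr8 stays open.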
